A study of Mus musculus with 20 samples.

How the data were processed

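Tail DNA of 10 mice of 1 C57BL/6 family, a sire, a dam and their 8 progeny, was compared with DNA of 1 reference male of the same colony on two-colour oligonucleotide arrays. Each mouse was hybridised in both dye orientations, which gave 20 arrays. The 2 arrays of a mouse were a technical dye swap, so they were averaged and counted as 1 replicate. The groups were the sire (n = 1), the dam (n = 1) and the progeny (n = 8). The title of the series names males given gamma rays at 0.05 mGy per day for 400 days, whereas its description of the design calls the male of this family non-irradiated. The exposure of the sire therefore stayed open, and the series held 1 family, so no rate was compared between exposed and unexposed families. The denser follow-up arrays and the quantitative PCR assays named in the design were not used here.

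Per the file headers, the spots were quantified with Agilent Feature Extraction 10.7.1.1, with probe positions on the mouse genome build mm9. The deposited processed signals are intensity values that the software had background-subtracted, spatially detrended and scaled linearly between dyes, with no lowess step. The deposited median spot and local background signals are raw intensity values. The deposited scanner log ratio is the log10 of red over green signal. The deposited matrix of values holds the log2 of reference over mouse on every array, which was found by setting each column against the scanner log ratio (Pearson r 0.989 to 1.00 in size across probes, which are not independent replicates).

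Spots on each array that were not controls numbered 966371, for 950749 distinct probes. Of these, 950622 lay on the 19 autosomes, 68 on X, 23 on Y and 36 on unplaced sequence, at a median spacing of 2053 bp. The log2 ratio of mouse over reference was taken from the processed signals. Spots with outlier or manual flags were left out (118 to 300 per array), while saturation flags were not used. Repeated spots of a probe were averaged, and each array was centred on its autosomal median. Median signals were 952 to 1008 in the mouse channel and 954 to 1007 in the reference channel. The median spot was 3.49 to 8.55 times the local background in Cy3 and 3.02 to 4.34 times in Cy5, and 99.3% to 99.9% of spots were well above background in both dyes. The SD of single probes was 0.20 to 0.33 on the log2 scale. For arrays, the number of arrays and of probes limits the precision.

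Intervals were called in each mouse by scanning windows of 3 to 500 consecutive probes. The score of a window was its mean log2 times the square root of its number of probes, divided by a robust SD of single probes. The highest-scoring windows that did not overlap were kept where the score was at least 6 in size, the mean at least 0.25 in size, and the mean at least 0.2 in the same direction in each orientation. Overlapping intervals of 1 direction were merged over mice into regions with the borders of the highest score. A mouse carried a region when its mean was at least 0.15 in size in the direction of the region and had that sign in both orientations. A region was absent from both parents when neither parent carried it by this rule. A parent with a mean of 0.15 or more in size in the direction of the region thus counted as not carrying it when its orientations differed in sign. The same scan was run on the halved difference between the orientations, less its mean over the 10 mice, in which a copy number change cancels. This was the comparison chosen beforehand for the count without copy number change. The scan was also run on probes in random order within each chromosome, 20 times, a comparison added after the calls had been seen. For a simulation, intervals were put into the real probes in random order, with local slide patches (defined below) left out. Each of the 10 mice received 20 intervals of each kind at the same positions, 200 in all, so a share by mouse rests on 20 intervals. The scan found 60% of gains of 0.5 over 3 probes (5% to 85% by mouse) and 99% of losses of 1 log2 unit over 3 probes. It found 91.5% of gains of 0.5 over 5 probes (60% to 100% by mouse) and 100% of all intervals of 10 or more probes.

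Transmission was tested for regions chosen from the parents alone, called in exactly 1 parent and not carried by the other. The test was a two-sided exact binomial test of the number of carriers among 8 progeny against a share of 0.5, with Benjamini-Hochberg adjustment. Progeny and parents were compared with limma on 95054 autosomal bins of 10 consecutive probes, 8 mice against 2, and bins with an adjusted p under 0.05 were counted. In 1 simulation with changes in 100 bins of each size, limma recovered 92% at 0.3 and 100% at 0.6 on the log2 scale. There were 3 false calls in all. The simulated values were independent normal values with the spread of the real progeny, so they held no structure shared between arrays. Scan dates were read from the file headers: the parents shared 1 of the 5 dates and the progeny were scanned in pairs, 1 and 2, 3 and 4, 5 and 6, and 7 and 8. Each date thus held mice of 1 generation only, so no comparison of progeny with parents could be made within a date, and scan date entered limma as a random block in an alternative.

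The caller, the tests, the regions to name and the alternative settings, apart from the exceptions stated here, were chosen before the data were examined. The regions to name were the 20 largest in size of mean log2 among regions absent from both parents and the 20 largest among regions in parents or in all mice. For the second list, "in parents" was read as called in a parent or carried by all 10 mice after the calls had been seen. Regions are named by mm9 position because the gene annotation at hand was on another build, so no gene is named and the intended comparison of gene lists was not run. Features named outside these lists were chosen after their values were seen. Alternatives changed the score, size, orientation and carrier thresholds, the fewest probes, flagged and dim probes, bins, dyes, mice and the source of the ratios. They included a running median over 1001 probes and normexp background correction with an offset of 50, which used median spot signals because the files held no mean signal. Chosen after seeing the data were the alternatives that left out local patches of the slide, asked for a median of at least 0.2 in each orientation, or left progeny 1 and 2 out of the counts. The residual of a spot was its log2 ratio with the dye bias of its probe taken off, centred on the array median. That dye bias was the mean over the 10 mice of the halved difference between orientations. A patch was a place where the median residual of the 9 by 9 spots around a spot exceeded 0.15 in size. Unusual mice were sought among the 8 progeny with Dixon's criterion at 0.526.

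Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.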

Results

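DNA copy number was measured along the autosomes in 10 mice of 1 family, each set against the same reference male in both dye orientations. The family comprised the sire, the dam and progeny 1 to 8. The series asks whether progeny of males under continuous low-dose gamma rays carry copy number changes, and these arrays were its primary screen. Every value for a mouse is the mean of its 2 arrays, and the mice were single animals without biological replicates except as 8 progeny. SE is the error over the probes of a region and SD the spread between the 2 arrays.

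The X and Y probes, which check the labels, split the family into 3 mice and 7 mice. X probes stood at a mean log2 of 0.90 ± 0.09 (SD) in the dam, 0.91 ± 0.07 in progeny 7 and 0.90 ± 0.07 in progeny 8 relative to the reference male. Y probes stood at -1.68 ± 0.05 in the dam, -2.02 ± 0.37 in progeny 7 and -1.82 ± 0.25 in progeny 8. The sire and progeny 1 to 6 lay between -0.01 and 0.03 on X and between -0.08 and 0.03 on Y. The dam is labelled female and the sire and reference male, while the sexes of the progeny are not labelled. A ratio of 2 copies to 1 is a log2 of 1. With normexp background correction the X level was 0.58 in the dam, 0.58 in progeny 7 and 0.59 in progeny 8.

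**Figure D1:**
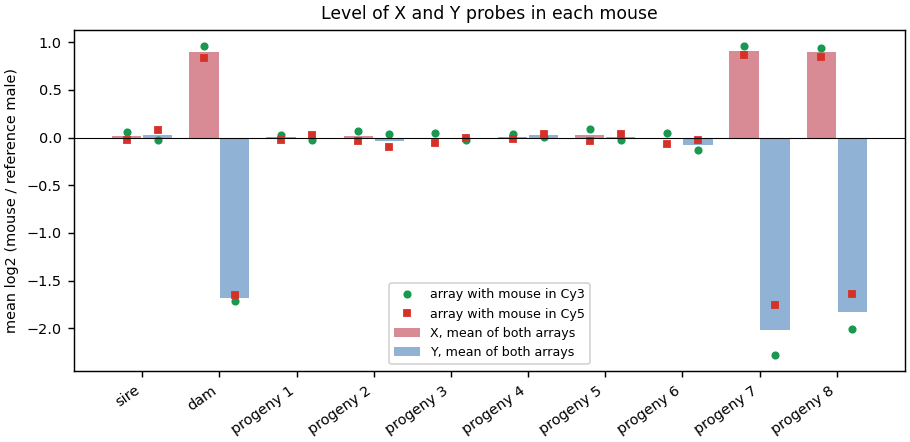
Bars give the mean log2 ratio of mouse over reference male for X and Y probes in each of the 10 mice, and points give the single arrays by the dye of the mouse. The dam, progeny 7 and progeny 8 stand at 0.90 to 0.91 on X and at -2.02 to -1.68 on Y, and the other 7 mice lie near 0 on both.

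One large gain on chromosome 4, from 101110482 to 101276346 and 166 kb long, was present in the sire and in 4 of the 8 progeny. Over its 76 probes the mean log2 was 0.50 ± 0.02 (SE) in the sire, 0.51 ± 0.03 in progeny 1, 0.55 ± 0.02 in progeny 3, 0.55 ± 0.02 in progeny 4 and 0.53 ± 0.02 in progeny 5. The dam stood at 0.00, progeny 2 at -0.03, progeny 6 at -0.05, progeny 7 at -0.01 and progeny 8 at 0.02. For scale, 3 copies against 2 give a log2 of 0.58 and 4 against 3 give 0.42. In the sire 94.7% of the probes of the region lay above 0.25, and in the dam 2.63% did. Called separately, the gain ran from 101107131 to 101274167 in the sire and progeny 1, and over the full borders given above in progeny 3, 4 and 5. It reached 4 of 8 progeny (exact binomial p = 1, adjusted p = 1). The region was the largest by number of probes in the whole scan, and it was picked out after its values were seen because it lies outside the lists of 20.

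**Figure D2:**
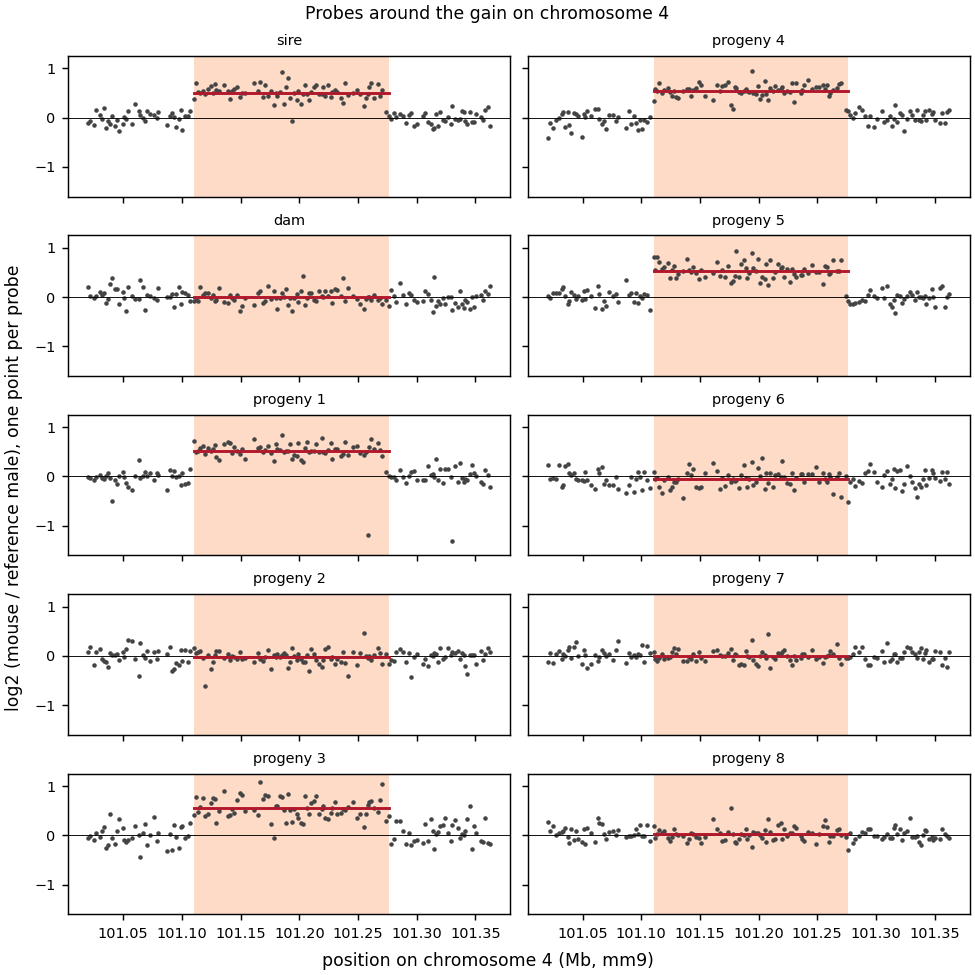
Log2 ratio of mouse over reference (y axis) by mm9 position in Mb (x axis) around the gain on chromosome 4, 1 panel per mouse and 1 point per probe, with the region shaded and its mean as a line. The mean is 0.50 to 0.55 in the sire and progeny 1, 3, 4 and 5 and -0.05 to 0.02 in the other 5 mice.

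A second group of regions was shared by the dam, progeny 7 and progeny 8 and carried by no other mouse. It comprised 31 regions, of which 24 were called in the dam: 23 losses on 14 chromosomes and 1 gain. These are the same 3 mice whose X and Y probes differed from the reference. The largest loss, on chromosome 3 from 25417435 to 25444229 with 4 probes, had a mean log2 of -1.56 ± 0.25 (SE) in the dam, -1.50 ± 0.29 in progeny 7 and -1.48 ± 0.31 in progeny 8. The next, on chromosome 6 from 104238274 to 104242812, stood at -1.44 ± 1.22, -1.44 ± 1.30 and -1.39 ± 1.41 in these mice, so that its error over 3 probes was about as large as its mean. Losses in the dam ranged from -1.56 to -0.32, and 22 of the 23 spanned 3 or 4 probes. In 21 of the 23, the loss averaged over the probes other than the lowest was smaller than 0.25.

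The gain of this group lay on chromosome 8 from 102132083 to 102253497, 121 kb long with 43 probes. Its mean log2 was 0.27 ± 0.02 in the dam, 0.27 ± 0.02 in progeny 7 and 0.30 ± 0.02 in progeny 8, and between -0.06 and 0.03 in the other 7 mice. The only loss of 10 probes lay on chromosome 14 from 61799762 to 61815412. It stood at -0.32 ± 0.06 in the dam, -0.39 ± 0.08 in progeny 7 and -0.38 ± 0.05 in progeny 8, at -0.11 in progeny 6 and between -0.03 and 0.06 in the other mice. Both were picked out after their values were seen. The gain on chromosome 8 reached 2 of 8 progeny (exact binomial p = 0.289, adjusted p = 0.337).

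**Figure D3:**
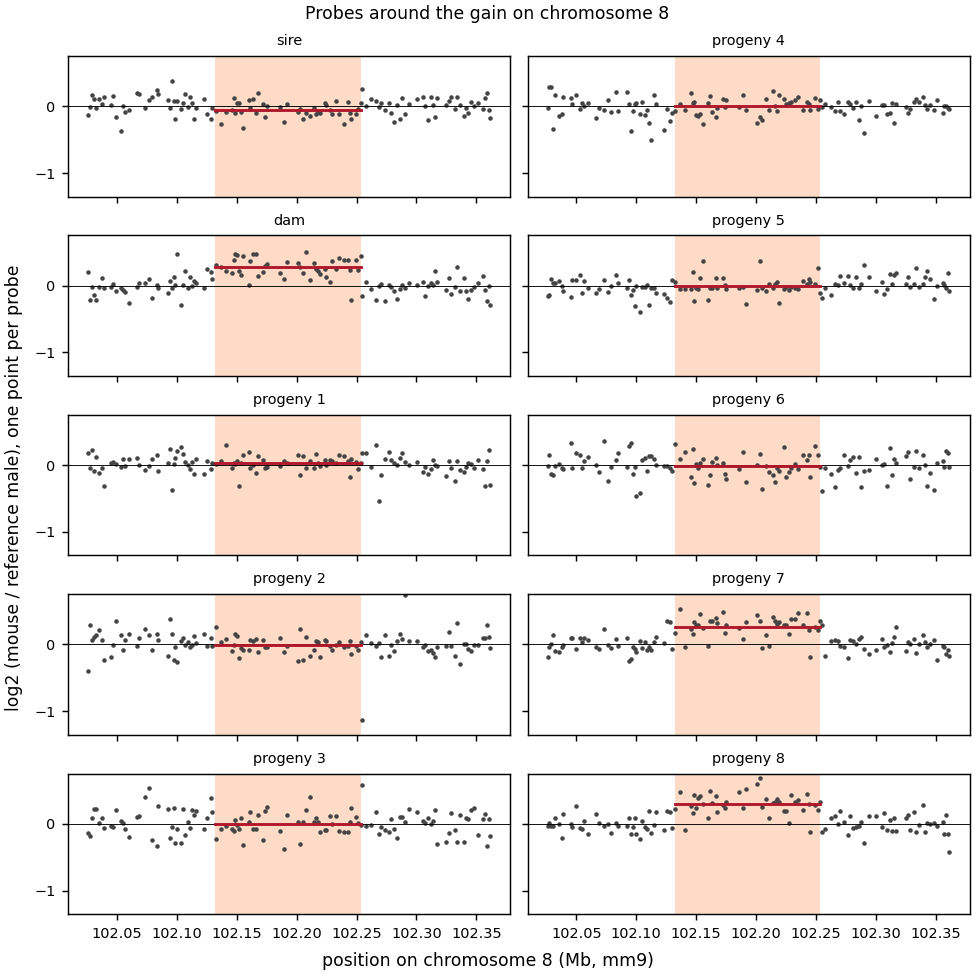
Log2 ratio of mouse over reference (y axis) by mm9 position in Mb (x axis) around the gain on chromosome 8, 1 panel per mouse and 1 point per probe, with the region shaded and its mean as a line. The dam, progeny 7 and progeny 8 stand at 0.27, 0.27 and 0.30, and the other 7 mice at -0.06 to 0.03.

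Of the 20 largest regions in parents, 12 were losses called in the dam, progeny 7 and progeny 8. Beside those on chromosomes 3 and 6, they included losses on chromosome 7 from 141017667 to 141020625 (-1.08 in the dam, -0.96 in progeny 7, -1.09 in progeny 8), chromosome 16 from 40849337 to 40854519 (-0.98, -0.91 and -1.17 in the same order) and chromosome 3 from 132546474 to 132549490 (-0.82, -0.95 and -1.09). The others of the 12 started at 35855832 on chromosome 9, 65227099 on chromosome 14, 59716785 on chromosome 11, 117625691 on chromosome 10, 3892507 on chromosome 4, 86061609 on chromosome 6 and 103998324 on chromosome 11. Another 3 were called in the dam alone: losses starting at 102012704 on chromosome 14 (-0.78), 18834955 on chromosome 7 (-0.77) and 46064318 on chromosome 14 (-0.72). The loss at 18834955 on chromosome 7 stood at -0.28 on the Cy3 array and -1.25 on the Cy5 array. It was no longer called with slide patches left out. A loss starting at 79025085 on chromosome 17 was called in the sire alone (-0.73). Losses starting at 126943608 on chromosome 7 and 138916792 on chromosome 6 were called in the dam, progeny 2 and progeny 8. Progeny 7 was not called but met the carrier rule at both (-0.29 and -0.30), as did progeny 4 at the second (-0.16). Their place in the list rests on progeny 2 (-0.80 and -0.78). Its Cy5 array stood at -1.45 and -1.35 there, and its Cy3 array at -0.15 and -0.21. A loss starting at 99255830 on chromosome 1 was called in the sire, the dam and progeny 1. A gain on chromosome 13 from 95703166 to 95707524, with 3 probes, was above 0 in all 10 mice. It ranged from 0.18 ± 0.40 (SE) in progeny 6 to 0.75 ± 0.69 in the sire, so its error in the sire was about as large as its mean. Progeny 6 stood at -0.01 on its Cy3 array and did not meet the carrier rule. In the sire, the median of the probes was under 0.2 in at least 1 orientation.

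Across all parental regions, 113 were called in exactly 1 parent and not carried by the other, 47 in the sire and 66 in the dam. No progeny carried 34 of them, 1 progeny carried 30, 2 progeny carried 33, 3 carried 9, 4 carried 7, and none reached 5 or more progeny. Progeny 7 and 8 were the sole carriers of 21, all of them from the dam. The exact binomial test against a share of 0.5 gave an adjusted p under 0.05 for 34 regions, 21 of the sire and 13 of the dam, each with 0 of 8 carriers (p = 0.00781, adjusted p = 0.0260). With 8 progeny, only 0 or 8 carriers could pass. Parental calls were about as many as probes in random order gave, 54 against 45 to 63 in the sire and 73 against 59 to 77 in the dam, so a region without carriers need not be a variant that was not passed on. Random windows of 3 probes met the carrier rule by chance in 1.84% to 7.39% of cases, depending on the progeny. With a carrier threshold of 0.25 the test passed 61 of 120 regions, and with 0.1 it passed 21 of 108.

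Called intervals per mouse were far more numerous in progeny 1 and 2 than in the rest of the family. Progeny 2 had 461 intervals, 413 of them losses, and progeny 1 had 319, 307 of them losses. The dam had 73, the sire 54, progeny 7 had 84, progeny 8 had 73, progeny 4 had 31, progeny 5 had 23, progeny 3 had 21 and progeny 6 had 12. With slide patches left out, simulated gains of 0.5 over 3 probes were found in 5% to 85% of cases depending on the mouse, so equal detection cannot be assumed for these counts. Detection with patches kept was not simulated. In all there were 1151 intervals, 980 losses and 171 gains. The halved difference between orientations, the comparison chosen beforehand, gave 542, fewer than the 1151 called. Probes in random order gave 1140 on average (1099 to 1189 over 20 runs), so the total was no larger than the spread of single probes gave without any order along the chromosome. Why these comparisons differed was not tested. Intervals of 10 or more probes numbered 14 when each mouse was counted, against 2.6 in random order (0 to 7). Merged over mice they formed 6 regions, which lay within the range in random order (2.6 on average, 0 to 7).

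**Figure D4:**
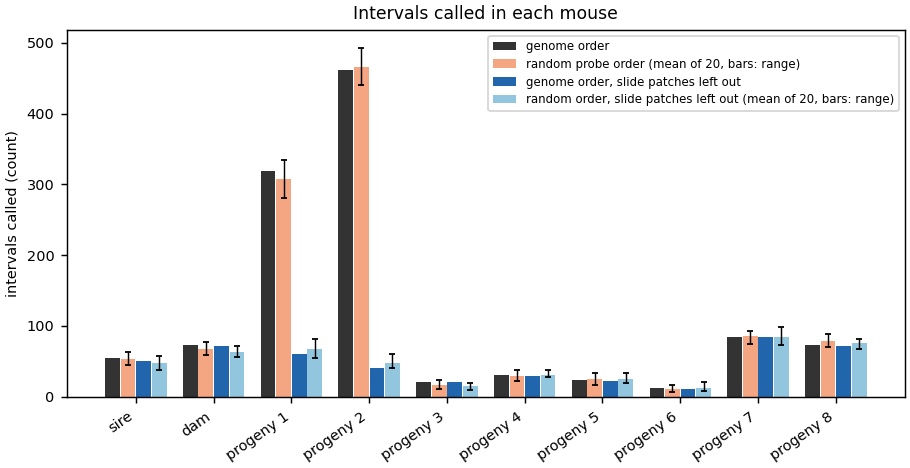
Intervals called (count, y axis) in each of the 10 mice with probes in genome order and in random order, with all spots and with local slide patches left out; the random-order bars are means of 20 runs and their error bars the range. Progeny 1 and 2 fall from 319 and 461 to 60 and 41 when patches are left out, and the other mice stay at 11 to 84.

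The low spots of progeny 1 and 2 lay together on the slides where these mice were labelled in Cy5. On the Cy5 array of progeny 2, 7670 spots had a residual below -1, and 90.2% of them touched another such spot where chance gave 6.18%. On the Cy5 array of progeny 1 there were 4200, of which 91.7% touched another, against 3.42% by chance. The next highest share was on the Cy5 array of the dam, where 36.7% of 458 low spots touched another, against 0.379% by chance. With spots in such patches left out, a step chosen after seeing the data, progeny 1 had 60 intervals, progeny 2 had 41, and the family had 461 against 468 in random order (441 to 498). Intervals of 10 or more probes then numbered 12 when each mouse was counted, against 0.95 in random order (0 to 3). Merged over mice they formed 4 regions, against 0.85 in random order (0 to 2).

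**Figure D5:**
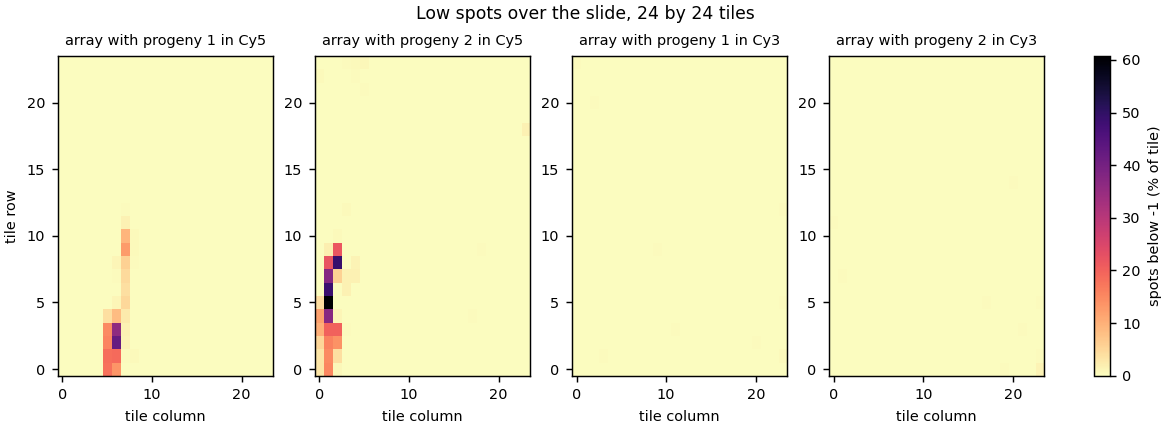
Share of spots with a residual log2 below -1, after the dye bias of each probe was taken off (percent of the tile, colour), over the surface of the slide (tile column and tile row). Both arrays of progeny 1 and progeny 2 are shown. The low spots stand in streaks on the 2 Cy5 arrays, which hold 4200 and 7670 of them, and the Cy3 arrays show none of these streaks.

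Regions absent from both parents, the comparison that addresses new copy number changes, numbered 849, of which 750 were losses and 99 gains. Progeny 1 or progeny 2 alone held 707 of them (83.3%). Progeny 2 had 420, progeny 1 had 292, progeny 7 had 44, progeny 8 had 35, progeny 4 had 21, progeny 3 had 17, progeny 5 had 17 and progeny 6 had 10. In 842 the call was in 1 progeny, 803 spanned 3 or 4 probes, and in 679 the mean of the probes other than the most extreme was under 0.25 in the direction of the region. The halved difference, the comparison chosen beforehand, gave 430, fewer than the 849 observed. Random probe order gave 829 on average (787 to 876), so the count did not exceed what unordered probes gave. Why these comparisons differed was not tested. With patches left out there were 213, 131 losses and 82 gains, against 222 in random order (201 to 246).

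All 20 of the largest such regions were losses in progeny 2, from -1.60 to -1.14. Leaving out patches kept 0 to 2 probes of each region on both arrays, fewer than the 3 a call needs. A call there could form only together with neighbouring probes, and 0 of the 20 were called again in progeny 2. With so few probes left, the lack of a call says little about these losses. The Cy3 arrays of progeny 2 then stood at -0.59 to -0.04 over these regions, and the spots left on the Cy5 array at -0.58 to 0.15, with none left for 1 region. The first 3 were on chromosome 7 from 141377529 to 141380227 (-1.60, with -0.28 on the Cy3 array and -2.91 on the Cy5 array), on chromosome 11 from 60534739 to 60539829 (-1.37) and on chromosome 16 from 35227908 to 35232518 (-1.36). At 1 of them, on chromosome 19 from 45301047 to 45305844 (-1.15 in progeny 2), an overlapping loss from 45305785 to 45310204 was then called in progeny 8 alone (-0.52). Progeny 1 to 6 stood between -0.41 and -0.27 there, and progeny 7 at 0.23. Regions of 10 or more probes absent from both parents numbered 3, against 2.3 in random order (0 to 6), and were picked out after their values were seen. These were losses on chromosome 16 from 17299629 to 17319529 (-0.53 ± 0.24 in progeny 2), chromosome 3 from 123963811 to 123981881 (-0.33 ± 0.17 in progeny 1) and chromosome 1 from 108442879 to 108470674 (-0.28 ± 0.10 in progeny 2, 16 probes). With patches left out, the loss on chromosome 1 was still called, at -0.30 over 15 probes, and the other 2 were not. The median of its probes was under 0.2 in size in at least 1 orientation, so the stricter requirement on the median was not met. With patches left out, random order gave 0.7 such regions on average (0 to 2).

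No bin of 10 probes passed the test of progeny against parents as groups. With limma, 0 of 95054 bins had an adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 2587 bins (2.72%). With scan date as a random block 0 bins passed, and the unadjusted count was 2138. With 2 parents on one side, and carriers of the gains on chromosomes 4 and 8 in both generations, this comparison addresses changes common to most progeny and not those of a single mouse.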

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

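Of the tests in this part, those on slide patches, random probe order, separate inheritance, single arrays and scan dates were chosen only after the results were seen. Single mice among the 8 progeny were sought in 12 sets of array measures and counts, of which 4 held a mouse far from the others, where chance alone gives about 1 in 20. They were also sought at 30 regions, of which 7 held such a mouse, but 6 of these 7 were chosen because that progeny was called there, so that rate does not apply to them.

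The SD of single probes on the Cy3 array was 0.33 in progeny 6, against 0.20 to 0.24 in the other progeny. On that array 0.145% of spots had a residual below -1, against 0.0180% to 0.0592%. The SD of single probes on the Cy5 array was 0.31 in progeny 3, against 0.21 to 0.25. Spots in slide patches on the Cy5 array made up 5.69% in progeny 2, against 0.102% to 2.06%. The next values mark regions picked because that progeny was called, so the distance from the other progeny is no separate evidence. Progeny 2 had the losses on chromosome 7 from 141377529 (-1.60), chromosome 11 from 60534739 (-1.37), chromosome 16 from 35227908 (-1.36), chromosome 16 from 17299629 (-0.53) and chromosome 1 from 108442879 (-0.28). Progeny 1 had the loss on chromosome 3 from 123963811 (-0.33). At a loss called in the dam, on chromosome 14 from 102012704, progeny 8 stood at -0.25, against -0.09 to 0.05 in the other progeny.

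Progeny 1 and 2 had 319 and 461 intervals, mostly losses, against 12 to 84 in the other mice. Losses that run along the chromosome are argued against, since random probe order gave 0.992 times as many calls in these 2 mice. Local patches on the slide are a candidate cause: with patches left out the larger of their counts was 60, within the range of the other mice, whose highest count was 84. The patches do not account for the loss on chromosome 1 from 108442879 in progeny 2, which was still called at -0.30 but whose median missed 0.2 in at least 1 orientation, and which might be a copy number loss or 1 of the 0 to 2 such regions that random order gave.

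The dam, progeny 7 and progeny 8 shared losses that no other mouse carried, and they are the mice with X probes near 0.90 and low Y probes. Separate autosomal variants inherited from the dam would reach different progeny, yet losses of 0.5 or more with exactly these 2 carriers lay on 10 chromosomes. Autosomal probes that also read Y sequence may explain the losses, while shared X sequence, at 0.90 in the dam, would raise them. Of 36 single probes at -1 or lower in the dam and above -0.25 in the sire, 94.4% were at -0.5 or lower in both progeny 7 and 8. No other pair of progeny passed 2.78%. These probes come from the same values as the losses, of which 21 of 23 rest on 1 low probe. The share is therefore no separate evidence and cannot tell Y sequence from another cause common to these mice. The sequences of the probes were not compared with Y. Progeny 7 and 8 shared a scan date and the dam was scanned on another. For the gain on chromosome 8 and the loss on chromosome 14, single regions of 43 and 10 probes, a variant of the dam and sequence shared with X (for the gain) or Y (for the loss) stay open.

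The gain on chromosome 4 in the sire and progeny 1, 3, 4 and 5 may be a heterozygous duplication of the sire, a hypothesis found and tested on the same data. An effect of dye or slide is argued against by the lowest single-array mean among these mice, 0.46 with patches left out. The caller already asked for 0.2 in each orientation, so only the height above 0.2 bears on this. A few probes that hybridise elsewhere are argued against by the 94.7% of probes above 0.25 in the sire. An effect of scan date is argued against by 3 dates on which the 2 mice differed by more than 0.3. The arrays cannot say whether the sire acquired the gain or inherited it, because its own parents were not measured here.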

How the results depend on the processing

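The tests chosen only after the results were seen are those with slide patches left out, with a median of 0.2 asked in each orientation, and without progeny 1 and 2. Intervals in the family (1151) and regions absent from both parents (849) moved to 2471 and 1720 at a score of 5, 416 and 325 at a score of 8, 474 and 363 with at least 5 probes, and 3859 and 3237 with no requirement on single orientations. They were 461 and 213 with patches left out, 396 and 273 with the median requirement, and 371 and 142 without progeny 1 and 2. Under the other alternatives intervals lay between 778 and 1222 and absent regions between 616 and 916, within 1.5 times the main count. Progeny 1 and 2 dominate these totals: counts of single mice moved by more in 8 of 10 mice with dim probes left out, 6 of 10 with normexp signals and 2 of 10 with a running median subtracted. With normexp signals the losses and gains were 810 and 27 for intervals and 660 and 11 for absent regions. Parental regions with an adjusted p under 0.05 (34) became 61 of 120 at a carrier threshold of 0.25 and 21 of 108 at 0.1, and were 33 with patches left out. The X level fell with normexp to 0.58 in the dam, 0.58 in progeny 7 and 0.59 in progeny 8, and the cause was not tested for this or for the changes above beyond their construction. Bins passing limma numbered 0 in all 23 settings, with 1424 to 28250 at an unadjusted p under 0.05. The settings were not all separate: the sire alone as the other group gave the same result as leaving out the dam. The dam alone likewise gave the same result as leaving out the sire. The gain on chromosome 4 moved most with normexp signals, to 0.48 in progeny 3. Gene lists were not run. Signal over background was lower in Cy5 (3.02 to 4.34). Leaving out dim probes gave 778 intervals, and a link between that count and the Cy5 signal was not tested.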

Other observations

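The test on other splits of the mice was chosen before its result was seen. Its repeat without slide patches and the regions named in this part were chosen only after the results were seen.

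On chromosome 14 from 53961688 to 53987490, 5 probes varied in both directions within the family. The mean log2 was 0.45 in the dam and 0.35 in progeny 7, and -0.49 in progeny 6, -0.29 in progeny 3 and -0.20 in progeny 1. In progeny 3 the 2 arrays had opposite signs there, 0.38 in Cy3 and -0.97 in Cy5. On 2 unplaced sequences, with 16 and 20 probes, the mean lay between -0.10 and 0.12 in the 10 mice. The gain on chromosome 8 stood at 0.27 to 0.30 in its carriers and the gain on chromosome 4 at 0.50 to 0.55.

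The comparison of progeny with parents called 0 bins, so all 45 splits of the 10 mice into 8 and 2 called at least as many by construction, and the splits say nothing about chance. The highest other split, with progeny 2 and 3 apart from the rest, called 118 bins. Another 3 splits called bins: 37 with progeny 2 and 6 apart, 17 with progeny 1 and 2, which share a scan date, and 2 with progeny 1 and 3. With slide patches left out, the splits with 118, 37 and 17 bins each called 0 with limma (3393 to 8775 bins at an unadjusted p under 0.05), while the one with progeny 1 and 3 apart called 13. New calls then came with the sire and progeny 3 apart (4 bins), the dam and progeny 8 (2) and progeny 3 and 7 (1). The calls that involve progeny 2 ended when patches were left out. The positions of the called bins were not examined, and the cause of the other calls was not tested. Effects of the arrays and copy number shared by the mice set apart both stay open for them.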
